A study of Mus musculus with 6 samples.

How the data were processed

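Poly(A)-selected RNA from mouse liver macrophages was sequenced in 6 libraries, 3 from mice on a high fat diet and 3 from mice on a normal diet. Both diets were given for 18 weeks, and the mice were about 6 weeks old at the start. Groups came from the treatment label of each sample. The design text counts mice, so each library was taken as 1 mouse. How the macrophages were isolated from the liver, and whether they were sorted, is not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol, mRNA was enriched on oligo(dT) beads, and cDNA was primed with random hexamers and amplified by PCR. The protocol names no step that keeps the strand, so overlapping genes on opposite strands may share reads.

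The authors deposited 1 table of 14918 genes with 4 kinds of values per gene. The raw read counts per library were deposited as whole numbers and were used for every test. A normalised signal per library was also deposited, and its ratio to the counts was 1 size factor per library, between 0.8852 and 1.183. Median-ratio factors recomputed from the counts differed from these by at most 0.33%. The deposited FPKM values rest on total counts slightly above those of the table, which holds between 99.831% and 99.937% of the reads behind them. The table also holds the authors' own comparison of the diets as a log2 fold change, and a p-value with an adjusted p-value that equals a Benjamini-Hochberg adjustment over its rows within 2.3e-05. The deposited log2 fold changes lie nearer to 0 than the ratio of group means for low or variable genes, for example 5.12 in the authors' deposited table against 6.81 for Cyp4a14. Per the submitters' processing notes, HISAT2, STAR, featureCounts, StringTie, edgeR, DESeq and STAR-Fusion were used with the mm10 build. Their versions, settings and order, and how reads that map to several genes were counted, are not given in the sources used here. Genes of near-identical families (Cyp2b, Cyp2c, Cyp4a, Gbp, Mup, Serpina1, H2) may therefore share or lose reads, and their values are uncertain. The gene with the lowest mean in the table had 7.02 normalised reads, so genes below about that level were not analysed here. No sample column was left unmatched to a label.

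Gene symbols were taken by Ensembl identifier from the GENCODE annotation of GRCm38, which matched 14842 of the 14918 genes, and the deposited name was kept for the other 76. All matched genes lay on the same chromosome in both, and 99.98% overlapped. Coordinates are those of the deposited table in mm10. Total counts per library lay between 17470439 and 23610956. Libraries of a group differed by far more than counting noise (chi-square per degree of freedom between 14.18 and 75.18 for the 6 pairs), so none was a repeat of another.

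The main test was edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default low-count filter, which left 14361 genes, and the quasi-likelihood test with a robust prior. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. The common biological coefficient of variation was 20.9% and the median prior degrees of freedom were 2.84. Expression is given as CPM, counts relative to the TMM-scaled library size, as mean ± SD with n = 3 libraries per group. The SE of a log2 fold change was the fold change divided by the square root of its F statistic. Where all libraries of a group held 0 counts, the fold is given as a lower bound against a floor of 3 counts per library, which covers counting error only.

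Before the data were examined, 38 lists of marker and pathway genes were fixed, along with the rule for the genes named. The rule took the 10 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM, a symbol that is not a predicted model, and groups that do not overlap. It also took the 3 members of smallest p in each list with a call, otherwise the 2 most abundant members, and 11 markers named in advance. Genes named only for a count adjusted over a list alone were chosen after their values were seen, and other genes outside the rule are marked so. Lists were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. A list score is the mean log2 CPM of its members, with a prior count of 2. Another 4 lists (hepatocyte lipid and xenobiotic response, interferon gamma response, type I interferon response, and genes taken as restricted to conventional dendritic cells) were written after the changed genes had been seen. So was the choice of all 16 tested genes of the Cyp2b, Cyp2c, Cyp3a and Cyp4a families, taken by symbol.

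Alternatives fixed in advance were median-ratio, upper-quartile and total-count scaling, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, the hepatocyte score as a covariate, and each library left out in turn. Added after seeing the data were edgeR without the robust prior, both tools without the libraries of highest and lowest hepatocyte score, and DESeq2 with each library left out. The scripts were tested on counts simulated for this comparison, with 200 of 14165 genes changed. In edgeR, 98% of the 8-fold and 64% of the 2-fold changes were recovered, with 10.5% false calls among 181. DESeq2 recovered 100% and 85%, with 26.3% false calls among 251, and limma voom 99% and 61%, with 7% false calls among 172. Figures were drawn with matplotlib 3.10.9.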

Results

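The study measured gene expression in macrophages taken from the livers of C57BL/6 mice after 18 weeks on a high fat diet or on a normal diet, with 3 mice in each group. The comparison asks how the transcriptome of liver macrophages differs between the diets. Apoe was the most abundant transcript in 4 libraries and Cd74 in the remaining 2, and Clec4f, the lectin that marks Kupffer cells (the resident macrophages of the liver), stood at 6570 ± 813 CPM on the high fat diet and 7920 ± 2250 CPM on the normal diet (SD, n = 3). Total counts were 20789786, 17470439 and 23610956 in high fat diet replicates 1 to 3, and 20362741, 19116659 and 19981476 in normal diet replicates 1 to 3.

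On the high fat diet, liver macrophage libraries held more RNA of the fatty acid scavenger receptor Cd36, of fibronectin (Fn1), the macrophage elastase Mmp12, the coagulation factor gene F13a1 and the calprotectin subunits S100a8 and S100a9. Fatty acid and drug metabolising enzymes of hepatocytes (Cyp4a14, Cyp4a10, Cyp3a11) rose too. The integrin Itgae (CD103), the growth factor Hbegf and the interferon-inducible GTPase gene Gbp2b fell. Gbp2b was deposited as Gbp5, over a model that also spans Gbp7 and Gbp3. Cd36 rose from 176 ± 20.7 to 596 ± 87.1 CPM (SD, n = 3), 3.39-fold, and Itgae was 4.37-fold lower. Of 14361 genes tested, 91 passed an edgeR adjusted p of 0.05, 64 higher and 27 lower on the high fat diet, and 57 of them changed at least 2-fold (50 higher, 7 lower). Where a pair of CPM values or scores follows without a diet, the normal diet comes first.

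In these 91 genes, the 3 libraries of one diet all lay above the 3 of the other. Such a separation was seen in 25.3% of all genes tested. Averaged over all splits of 3 against 3, the share is 10% for genes without ties. Genes that vary together can take a single split far from 10%. The share in the other splits was not counted, so the excess cannot be judged. All 91 also passed in the authors' deposited table, in the same direction, where 1191 genes had an adjusted p under 0.05. DESeq2 on the same counts called 1198 genes (733 higher, 465 lower), the 91 among them. The edgeR count fell to 4 without high fat diet replicate 1, to 0 without replicate 2 (1962 genes at an unadjusted p under 0.05; DESeq2 750), to 2 without replicate 3, to 0 without normal diet replicate 1 (2002 genes; DESeq2 832) and to 22 without normal diet replicate 3. Without normal diet replicate 2 it was 1385 (519 higher, 866 lower), with all 91 among them. Counts of list members given below without that library come from this setting, which called the most genes of any library left out.

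**Figure D1:**
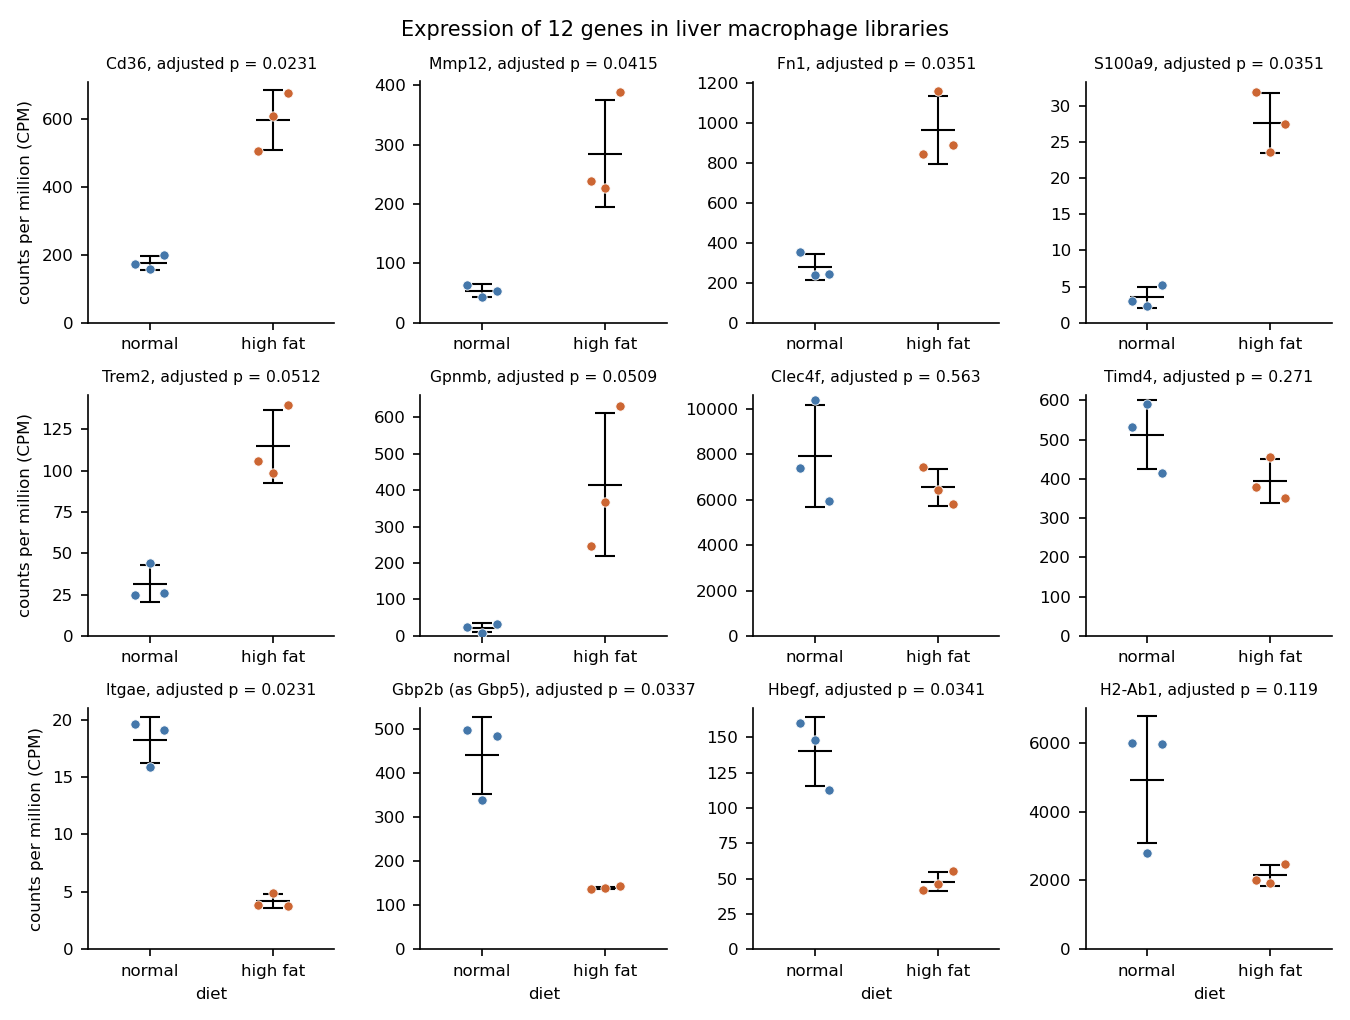
Expression of 12 genes in CPM on linear axes that start at 0, with 1 point per library, the mean as a horizontal bar and the SD as error bars (n = 3 per diet); each title gives the edgeR adjusted p. Cd36, Mmp12, Fn1 and S100a9 lay higher and Itgae, Gbp2b (deposited as Gbp5) and Hbegf lower in all 3 high fat diet libraries, while Clec4f and Timd4 overlapped between the diets.

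Genes of lipid-associated macrophages, a state described in obese tissue, stood higher on the high fat diet in 21 of the 23 members tested, with a median log2 fold change of 0.84. Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888959, mm10) and Mmp12, the macrophage elastase (chromosome 9, 7344381 to 7369499), rose by log2 fold changes of 1.76 ± 0.14 (SE, edgeR adjusted p = 0.0231) and 2.41 ± 0.27 (0.0415). Gpnmb, a lysosomal glycoprotein, was at 21.8 ± 12.3 and 415 ± 197 CPM and the lipid receptor Trem2 at 31.5 ± 11.1 and 115 ± 22 CPM (SD, n = 3), and both just missed the threshold (adjusted p = 0.0509 and 0.0512 in edgeR). Spp1, at 23.7 ± 12.1 and 123 ± 49.5 CPM, and Cd9, at 48.0 ± 19.4 and 85.9 ± 23 CPM, did not pass (0.0927 and 0.276). Over the list, 2 genes rose and none fell after adjustment over all genes, and 16 rose adjusted over the list alone. Over all genes, 7 rose without normal diet replicate 2, and 0 or 1 with any other library left out. With all libraries DESeq2 called 14. The list stood apart from other genes in camera with the preset correlation (adjusted p = 7.72e-20) but not with an estimated correlation (adjusted p = 0.264).

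Genes of monocytes and recruited macrophages showed 2 of 18 members higher and none lower over all genes, and 8 higher adjusted over the list alone. Without normal diet replicate 2, 4 were higher and 2 lower, and the list median was 0.26 against 0.54 (0.88 without normal diet replicate 3). With all libraries, the members past the threshold were Fn1, fibronectin (chromosome 1, 71585520 to 71653200), at 278 ± 64.0 and 964 ± 168 CPM, and F13a1, the A chain of coagulation factor XIII, at 34.0 ± 7.21 and 98.8 ± 10.6 CPM (SD, n = 3; edgeR adjusted p = 0.0351 for each). Chil3 was at 8.02 ± 4.65 and 57.2 ± 18.4 CPM and the chemokine receptor gene Ccr2 at 98.7 ± 33.2 and 221 ± 70.5 CPM without passing (0.0752 and 0.144). Camera gave an adjusted p of 7.72e-07 with the preset correlation and 0.335 with an estimated correlation. Of 22 extracellular matrix and remodelling genes, Fn1, Mmp12 and the neutrophil collagenase Mmp8 rose and none fell, with the same 3 adjusted over the list alone, and the camera adjusted p was 0.0540 (higher, at 0.00118 without high fat diet replicate 1 and 0.000513 without normal diet replicate 1). The list's median was near 0 (log2 0.01) and reached 0 or below under median-ratio and upper-quartile scaling. It was -0.11 without normal diet replicate 2 and 0.42 with the hepatocyte score as a covariate.

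Neutrophil markers gave the highest median of the 38 lists, at a log2 fold change of 2.23 over 16 genes. S100a9 rose from 3.49 ± 1.51 to 27.7 ± 4.14 CPM, S100a8 from 2.6 ± 1.04 to 15.0 ± 1.65 CPM, and Mmp8 from 0.977 ± 0.419 to 6.09 ± 1.2 CPM (SD, n = 3; edgeR adjusted p = 0.0351, 0.0351 and 0.0430). These 3 rose and none fell over all genes, while 12 rose and 1, Il1r2, fell adjusted over the list alone (7 and 1 over all genes without normal diet replicate 2). Camera gave an adjusted p of 2.67e-16 with the preset correlation and 0.264 with an estimated correlation.

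Markers of resident and of all macrophages had list medians of log2 -0.23 and -0.04, which were not tested against those of the lists above. None of 24 Kupffer cell identity genes passed in edgeR (4 at an unadjusted p under 0.05, all lower; 2 lower in DESeq2, 0 in limma voom), and 2, Id3 and Ccl24, fell adjusted over the list alone. Clec4f had a log2 fold change of -0.27 ± 0.23, Cd5l of 0.09 ± 0.17, Timd4, which marks long-lived resident Kupffer cells, of -0.38 ± 0.16 and the complement receptor Vsig4 of -0.23 ± 0.23 (SE). Camera with the preset correlation called the Kupffer list lower (adjusted p = 0.00431; 0.646 without normal diet replicate 2, where 1 gene rose, 2 fell and the median was -0.07 against -0.23), with an adjusted p of 0.612 with an estimated correlation. Of 18 genes common to macrophages, Itgam (CD11b) rose from 195 ± 3.52 to 314 ± 27.8 CPM (SD, n = 3; edgeR adjusted p = 0.0420), and 2 rose adjusted over the list alone, Itgam and the fractalkine receptor Cx3cr1, which stood at 32.7 ± 1.60 and 107 ± 37.6 CPM and missed the threshold over all genes (0.05007). Adgre1 (F4/80), Cd68 and C1qa had log2 fold changes of 0.19 ± 0.19, 0.16 ± 0.13 and -0.32 ± 0.16. The list's camera adjusted p was 0.558; its median (log2 -0.04) and its mean (0.08) differed in sign.

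**Figure D2:**
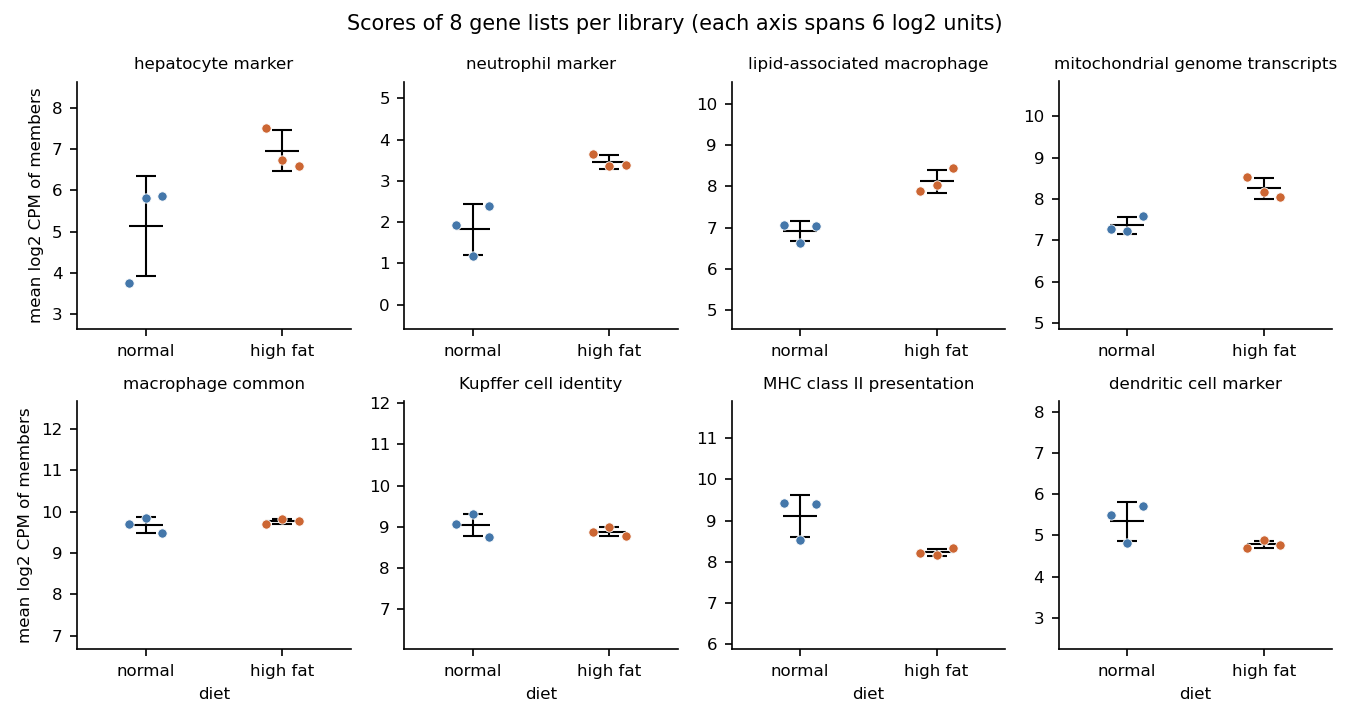
Mean log2 CPM of the members of 8 gene lists, with 1 point per library, the mean as a horizontal bar and the SD as error bars (n = 3 per diet); every axis spans the same number of log2 units, at different heights. Hepatocyte marker scores ran from 3.75 to 5.85 on the normal diet and from 6.60 to 7.52 on the high fat diet, while common macrophage scores overlapped.

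Hepatocyte transcripts stood higher in the high fat diet libraries and varied widely within the diets. Alb, the most abundant hepatocyte mRNA, was at 3760 ± 1100 CPM on the high fat diet and 1150 ± 713 CPM on the normal diet (SD, n = 3; edgeR adjusted p = 0.193). All 34 hepatocyte markers had positive log2 fold changes (median 1.60), of which 1 passed over all genes, Cyp3a11, and 5 adjusted over the list alone (Cyp3a11, Cyp7a1, Hp, Apob and Apoh). Hp was at 43.8 ± 24.4 and 248 ± 58.1 CPM and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.509 ± 0.230 and 6.42 ± 4.59 CPM, and neither passed (0.0844 and 0.0842). The hepatocyte score was 7.52, 6.74 and 6.60 in high fat diet replicates 1 to 3 and 3.75, 5.81 and 5.85 in normal diet replicates 1 to 3. The leading principal component of the 500 most variable genes held 82% of their variance and ranked high fat diet replicate 1 at one end and normal diet replicate 1 at the other, as the hepatocyte score did. Camera gave the list an adjusted p of 2.87e-17 with the preset correlation and 0.359 with an estimated correlation. With the hepatocyte score as a covariate, edgeR called 0 genes for diet (1046 at an unadjusted p under 0.05, smallest adjusted p = 0.131). All 91 genes kept their sign and an unadjusted p under 0.05, but the calls ended. These genes had been selected for a diet difference in the same libraries, so their sign is no independent support. The hepatocyte scores of the diets did not overlap, so the fit cannot fully separate score from diet. The SE was larger for 86, with 3 residual degrees of freedom against 4. Over the 91, the median absolute log2 fold change was 1.47 without and 1.29 with the covariate, and the median SE 0.16 and 0.23. The log2 fold change was 1.76 ± 0.14 without and 1.84 ± 0.24 with the covariate for Cd36, 1.79 ± 0.20 and 2.29 ± 0.22 for Fn1, 1.54 ± 0.16 and 1.96 ± 0.17 for F13a1, 2.41 ± 0.27 and 2.87 ± 0.36 for Mmp12 (SE). For Itgae it was -2.13 ± 0.16 and -1.98 ± 0.24. For Cyp4a14 it was 6.82 ± 0.51 and 5.63 ± 0.65, and for Cyp3a11 3.27 ± 0.44 and 2.24 ± 0.39. Of the 105 named genes, 8 differed in sign with the covariate, all without a call, and 1 of these, Cxcl2, had an unadjusted p under 0.05. Without high fat diet replicate 1 and normal diet replicate 1, a choice made after seeing the data, edgeR called 0 (1384 at an unadjusted p under 0.05) and DESeq2 417, 77 of them among the 91.

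Among genes past the threshold with a mean of at least 5 CPM, the largest rises were in genes that hepatocytes express. Cyp2b9, a xenobiotic-metabolising cytochrome P450, had 11.7 ± 4.09 CPM on the high fat diet (SD, n = 3) and 0 counts in all normal diet libraries, at least 76.3-fold higher against a floor of 3 counts per library. Cyp4a14 and Cyp4a10, fatty acid hydroxylases induced by PPAR alpha, rose by log2 fold changes of 6.82 ± 0.51 and 4.76 ± 0.57 (SE; edgeR adjusted p = 0.0244 and 0.0420). Cyp4a14 (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142) rose from 0.413 ± 0.285 to 46.7 ± 19.0 CPM. Dio1, a thyroid hormone deiodinase, Serpina6, the corticosteroid-binding globulin, Apoa4, Cyp3a11 and the retinaldehyde dehydrogenase Aldh1a1 rose between 8.30-fold (Aldh1a1) and 23.8-fold (Dio1). The Cyp2b and Cyp4a genes have close paralogs, so reads may be split among them. In the same libraries the hepatocyte score was 5.14 ± 1.20 and 6.95 ± 0.50 (SD, n = 3).

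Each of 4 lipid metabolism lists held 1 or 2 calls, all higher, in libraries that also held more hepatocyte RNA. Of 28 fatty acid oxidation genes, 26 had positive log2 fold changes, 2 rose over all genes and 21 adjusted over the list alone. Etfa, an electron carrier subunit of beta-oxidation, rose 1.49-fold and Hadha, a subunit of the trifunctional protein, 1.39-fold (edgeR adjusted p = 0.0431 and 0.0436), and Eci1 stood 1.8-fold higher without passing (0.0584). Of 21 genes for lipid uptake, storage and transport, Cd36 and the lipid droplet protein gene Cidec rose (10 adjusted over the list alone). Cidec rose from 0.0831 ± 0.103 to 2.88 ± 1.28 CPM (SD, n = 3; log2 fold change 4.99 ± 0.75, SE, edgeR adjusted p = 0.04996), and G0s2, an inhibitor of lipolysis, was at 8.74 ± 3.54 and 26.0 ± 3.98 CPM without passing (0.0800). Of 19 fatty acid synthesis and desaturation genes, Acaca (acetyl-CoA carboxylase) rose 1.40-fold (0.0481), 7 adjusted over the list alone, and Me1 and Fads2 stood 4.55-fold and 3.92-fold higher without passing (0.0754 and 0.0887). Their log2 fold changes were 2.19 ± 0.42 and 1.97 ± 0.41 without and 1.16 ± 0.42 and 0.87 ± 0.27 with the hepatocyte score as a covariate (SE). Of 18 LXR target and cholesterol efflux genes, the phospholipid acyltransferase gene Lpcat3 rose 1.45-fold (0.0481), 4 adjusted over the list alone (with Npc1, Abcg1 and Abcg5), while Npc1 and Abcg1 stood 1.40-fold and 1.35-fold higher without passing over all genes. Camera adjusted p-values of these 4 lists with the preset correlation were 1.01e-12, 1.02e-10, 1.37e-06 and 0.00431, and with an estimated correlation the adjusted p-values were 0.272, 0.163, 0.302 and 0.285. When normal diet replicate 2 was left out, 11, 5, 1 and 3 genes of these lists rose, in the order given. In each of the second and the third, 1 fell.

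Mitochondrially encoded transcripts took 3.327%, 2.573% and 2.350% of the counts in high fat diet replicates 1 to 3 and 1.330%, 1.515% and 1.980% in normal diet replicates 1 to 3. None of the 12 tested passed in edgeR over all genes (12 at an unadjusted p under 0.05, all higher; DESeq2 11, limma voom 0), and 12 rose adjusted over the list alone. mt-Cytb stood at 2180 ± 654 and 4760 ± 1090 CPM and mt-Co1 at 8870 ± 1490 and 13300 ± 2020 CPM (SD, n = 3). The list's median log2 fold change was 0.98 without and 0.41 with the hepatocyte score as a covariate, and 4 genes rose without normal diet replicate 2. Camera gave an adjusted p of 9.68e-14 with the preset correlation and 0.285 with an estimated correlation. None of the 40 nuclear genes of oxidative phosphorylation passed in edgeR (8 higher and 1 lower at an unadjusted p under 0.05; DESeq2 1, limma voom 0; none adjusted over the list alone). Their median log2 fold change was 0.06, and Atp5a1 and Atp5b stood at 0.20 ± 0.08 and 0.01 ± 0.10 (SE). Atp5b rounded to 0 under median-ratio and upper-quartile scaling.

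Antigen presentation genes stood lower on the high fat diet. All 11 MHC class II presentation genes had negative log2 fold changes, with a median of -1.08, and none passed in edgeR over all genes (9 at an unadjusted p under 0.05; DESeq2 8 lower, limma voom 0), while 9 fell adjusted over the list alone. Cd74, the invariant chain, was at 12400 ± 3210 CPM on the normal diet and 6320 ± 821 CPM on the high fat diet, and H2-Ab1 at 4940 ± 1840 and 2140 ± 301 CPM (SD, n = 3; edgeR adjusted p = 0.101 and 0.119). Normal diet replicate 2 lay nearest to the high fat diet libraries. Without it 10 of the 11 genes fell, against 0 with any other library left out. With the hepatocyte score as a covariate the list's median was -0.68. All 13 MHC class I presentation genes had negative log2 fold changes (median -0.61), none passed in edgeR (11 at an unadjusted p under 0.05; DESeq2 9, limma voom 0), and 10 fell adjusted over the list alone; H2-D1 and B2m were at -0.35 ± 0.11 and -0.27 ± 0.11 (SE). Without normal diet replicate 2, 9 of the 13 fell, against 0 with any other library left out. Camera gave adjusted p-values of 6.6e-10 and 4.22e-09 with the preset correlation, and adjusted p-values of 0.302 and 0.359 with an estimated correlation.

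Dendritic cell markers showed 1 of 19 members lower, Itgae, none higher, and 5 lower adjusted over the list alone (Itgae, Xcr1, Clec9a, Irf8 and Irf4). With normal diet replicate 2 left out, 10 of the 19 fell over all genes, and the list median was -0.88 against -0.57 (-0.31 without normal diet replicate 3). Itgae (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446), which marks conventional type 1 dendritic cells and tissue T cells, fell from 18.2 ± 1.97 to 4.17 ± 0.604 CPM (SD, n = 3; edgeR adjusted p = 0.0231). Clec9a and Xcr1, markers of the same dendritic cells, stood 1.73-fold and 2.40-fold lower without passing over all genes (0.0610 and 0.0676). Camera gave an adjusted p of 1.52e-08 with the preset correlation and 0.359 with an estimated correlation. Of 30 interferon-stimulated genes, none passed in edgeR (9 lower at an unadjusted p under 0.05; DESeq2 7 lower, limma voom 0), 7 fell adjusted over the list alone, and 9 fell over all genes without normal diet replicate 2. Irf7 and Oas2 were at -0.17 ± 0.14 and 0.06 ± 0.17 (SE). Camera gave this list an adjusted p of 0.000131 with the preset correlation and 0.302 with an estimated correlation.

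Further genes fell. Among those with a mean of at least 5 CPM, leaving out predicted and clone-named genes, the largest changes besides Itgae were in Cnbd2, from 41.9 ± 9.43 to 9.35 ± 1.86 CPM, Gbp2b, from 440 ± 87.6 to 139 ± 2.95 CPM, and Hbegf, an EGF family growth factor, from 140 ± 24.1 to 47.8 ± 6.77 CPM (SD, n = 3; edgeR adjusted p = 0.0337, 0.0337 and 0.0341). Gbp2b was deposited as Gbp5, with a gene model on chromosome 3 from 142496934 to 142619179 that spans the reference positions of Gbp5, Gbp7, Gbp3 and Gbp2b, so its counts may come from any of the 4. The ion transport genes Slc12a5 and Atp1b3 fell 2.17-fold and 1.87-fold. Srcin1, She, Tex14 and the phospholipase gene Pla2g16 fell between 1.86-fold and 1.98-fold.

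Immediate early and dissociation stress genes had negative log2 fold changes in all 21 members, with a median of -0.48. Egr1, a transcription factor induced within minutes of stimulation, fell from 219 ± 16.2 to 124 ± 13.3 CPM (SD, n = 3; edgeR adjusted p = 0.0420). The heat shock gene Hsph1 and the early response gene Ier3 each stood 1.85-fold lower without passing (0.0524 and 0.0676). Over all genes 1 member fell and none rose, but 10 fell without normal diet replicate 2 and 0 with any other library left out. With all libraries, 15 fell adjusted over the list alone. Camera gave an adjusted p of 5.16e-14 with the preset correlation and 0.264 with an estimated correlation.

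**Figure D3:**
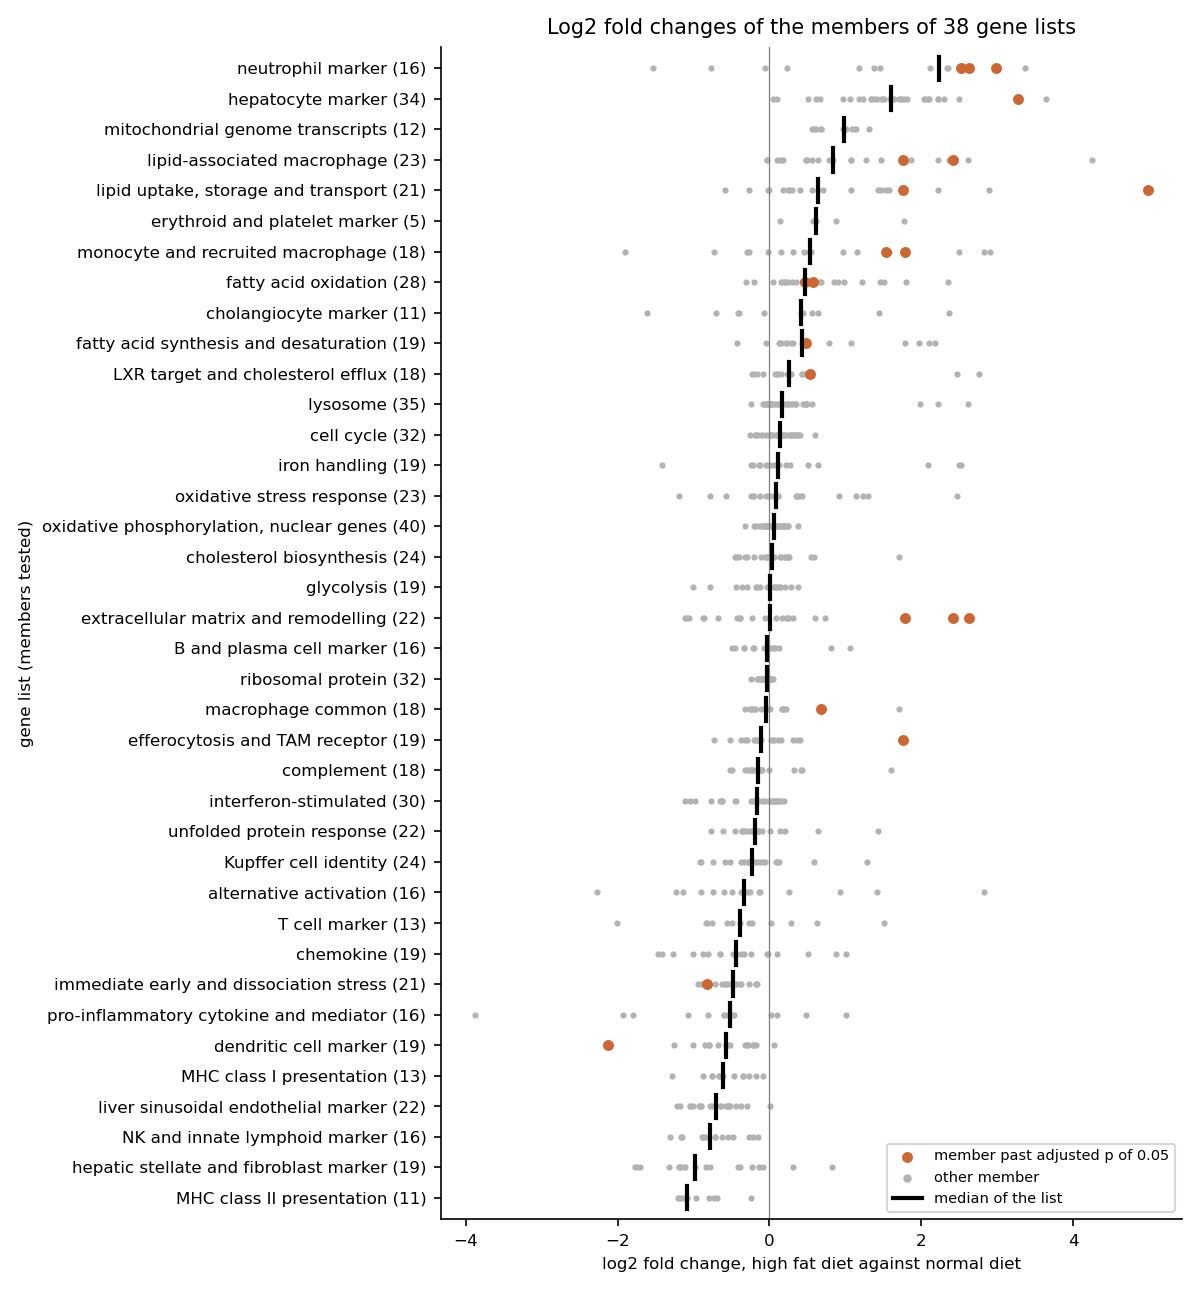
Log2 fold changes, high fat diet against normal diet, of the tested members of 38 gene lists fixed in advance, ordered by list median (black bars), with members past an edgeR adjusted p of 0.05 as larger orange points and other members in grey. Neutrophil markers (median 2.23) and hepatocyte markers (1.60) lay at the top and MHC class II genes (-1.08) at the bottom, and most lists held no gene past the threshold.

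Lists of inflammatory mediators held no call in edgeR with all 6 libraries. None of 16 pro-inflammatory cytokine and mediator genes passed in edgeR (1 higher and 10 lower at an unadjusted p under 0.05; DESeq2 5 lower, limma voom 0), with 1 higher (Il18) and 8 lower adjusted over the list alone. Il1b was at 759 ± 239 and 501 ± 20.8 CPM and Cd86 at 305 ± 58.1 and 217 ± 22.7 CPM on the normal and the high fat diet (SD, n = 3). Without normal diet replicate 2, 11 of the 16 fell, against 0 with any other library left out. None of 19 chemokine genes passed (2 higher and 7 lower at an unadjusted p under 0.05; DESeq2 1 higher and 2 lower, limma voom 0; none adjusted over the list alone; 1 rose and 4 fell without normal diet replicate 2), and Ccl6 and Cxcl2 were at -0.03 ± 0.18 and -0.02 ± 0.28 (SE), with Cxcl2 at 0.01 under total-count scaling and 0.73 ± 0.24 with the hepatocyte score as a covariate (unadjusted p = 0.0209). None of 16 alternative activation genes passed (4 higher and 7 lower at an unadjusted p under 0.05; DESeq2 3 and 6, limma voom 0; 2 rose and 8 fell without normal diet replicate 2), with 3 higher (Chil3, Arg1 and Pparg) and 7 lower adjusted over the list alone, and Cd163 and Mrc1 were at -0.12 ± 0.36 and -0.13 ± 0.12 (SE). Camera adjusted p-values for the 3 lists were 3.2e-05, 0.0170 and 0.0161 with the preset correlation, and 0.374, 0.493 and 0.374 as adjusted p-values with an estimated correlation. The preset-correlation call of the chemokine list was lost without high fat diet replicate 1 (0.120) or normal diet replicate 1 (0.300), and that of the alternative activation list without high fat diet replicate 3 (0.0502). Without both high fat diet replicate 1 and normal diet replicate 1, the adjusted p of these lists was 0.734 and 0.117. Of 19 efferocytosis and TAM receptor genes, Cd36 rose, also adjusted over the list alone (3 rose and 1 fell without normal diet replicate 2), and the bridging ligand gene Gas6 and Itgav were at -0.73 ± 0.18 and 0.36 ± 0.12 (SE). Its camera adjusted p was 0.558, and its median (-0.11) and mean (0.01) differed in sign.

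Markers of endothelial, stellate and lymphoid cells gave no call in edgeR with all 6 libraries. Of 22 liver sinusoidal endothelial markers, 21 had negative log2 fold changes (median -0.70, but -0.16 without normal diet replicate 3; 3 lower at an unadjusted p under 0.05; DESeq2 3 lower, limma voom 0), and Stab2 and Ptprb were at -0.51 ± 0.25 and -0.92 ± 0.42 (SE). Of 19 hepatic stellate and fibroblast markers, 17 were negative (median -0.98, but -0.40 without normal diet replicate 1 and 0.17 with the hepatocyte score as a covariate; 7 lower at an unadjusted p under 0.05; DESeq2 2 lower, limma voom 0), with Ecm1 at -0.08 ± 0.20 and Bgn at -0.83 ± 0.35. All 16 NK and innate lymphoid markers were negative (median -0.78, but 0.09 without normal diet replicate 3; 1 at an unadjusted p under 0.05; DESeq2 1, limma voom 0), with Klrk1 at -0.47 ± 0.12 and Ccl5 at -0.88 ± 0.46. None of these 3 lists had a call adjusted over the list alone, and their camera adjusted p-values of 6.7e-05, 0.00032 and 0.00723 with the preset correlation became 0.559, 0.493 and 0.654 as adjusted p-values with an estimated correlation. Without normal diet replicate 3 the preset-correlation adjusted p was 0.0615 for the endothelial and 0.834 for the NK list, and without high fat diet replicate 2 it was 0.0775 for the NK list. For the stellate list it was 0.181 without both high fat diet replicate 1 and normal diet replicate 1. Of the 3 lists, 3, 1 and 1 genes fell over all genes without normal diet replicate 2. T cell markers (13 genes, median -0.38, but 0.11 without normal diet replicate 3, 2 higher and 2 lower at an unadjusted p under 0.05, DESeq2 2 lower, limma voom 0) had 2 lower, Cd4 and Cd5, adjusted over the list alone, and Icos and Cd4 were at 0.63 ± 0.20 and -0.83 ± 0.20. B and plasma cell markers (16 genes, 2 higher at an unadjusted p under 0.05, DESeq2 2 higher, limma voom 0) had none, with a median of -0.02 that reached 0 under total-count scaling, and Ighm and Igkc were at 0.08 ± 0.22 and 0.01 ± 0.21. Cholangiocyte markers (11 genes, 3 higher and 1 lower at an unadjusted p under 0.05, DESeq2 1, limma voom 0) had 1 higher, Spp1, with Anxa4 at 0.42 ± 0.16. Erythroid and platelet markers (5 genes, 2 higher at an unadjusted p under 0.05, DESeq2 1, limma voom 0) had 1 higher, Alas2, with Pf4 at 0.87 ± 0.33 and Hbb-bs at 0.57 ± 0.41. Camera adjusted p-values for these 4 lists were 0.247, 0.912, 0.254 and 0.0252, the last with an adjusted p of 0.359 with an estimated correlation and of 0.0656 with the preset correlation without high fat diet replicate 1. Without both that library and normal diet replicate 1, the erythroid and platelet list had an adjusted p of 0.0981. The cholangiocyte list was called higher without normal diet replicate 3 (0.0467).

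Lysosomal and stress response genes gave no call in edgeR with all 6 libraries either. Of 35 lysosome genes, 28 had positive log2 fold changes (median 0.16, and 0.10 without normal diet replicate 3; 12 higher at an unadjusted p under 0.05; DESeq2 8 higher, limma voom 0), 7 rose adjusted over the list alone, and Ctsb and Psap were at -0.03 ± 0.19 and 0.29 ± 0.14 (SE). Of 22 unfolded protein response genes, 17 were negative (median -0.19; 1 higher and 7 lower at an unadjusted p under 0.05; DESeq2 3 lower, limma voom 0), 3 fell adjusted over the list alone (Ddit3, Ppp1r15a and Manf), and Hspa5 and Calr were at -0.36 ± 0.14 and -0.15 ± 0.10. In the absence of normal diet replicate 2, 8 lysosome genes rose and 4 unfolded protein response genes fell over all genes. Camera adjusted p-values of both lists were 3.89e-05 and 0.00111 with the preset correlation, and the adjusted p was 0.493 for each with an estimated correlation. Oxidative stress response genes (23 genes; 7 higher and 2 lower at an unadjusted p under 0.05; DESeq2 4 and 2, limma voom 0) had 6 higher and 2 lower, the metallothionein genes Mt1 and Mt2, adjusted over the list alone. Iron handling genes (19 genes; 5 higher and 1 lower at an unadjusted p under 0.05; DESeq2 4 and 1, limma voom 0) had 2 higher, Hamp and Hp, both made by hepatocytes. The ferritin genes Ftl1 and Fth1, in both lists, were at 0.12 ± 0.15 and -0.04 ± 0.16 (SE), and the lists' camera adjusted p-values were 0.150 and 0.0664. Both lists were called higher by camera without normal diet replicate 1 (0.0237 and 0.00412), as was iron handling without high fat diet replicate 3 (0.0483) or normal diet replicate 2 (0.0282).

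Housekeeping and growth lists held no call in edgeR with all 6 libraries. Ribosomal protein genes (32 genes, median -0.03, Rpl10 at -0.02 ± 0.09 and Rplp0 at -0.05 ± 0.13, SE) and cell cycle genes (32 genes, median 0.14, but -0.15 without high fat diet replicate 2, Pcna at -0.09 ± 0.09 and Hmgb2 at -0.14 ± 0.18) had 0 genes past an unadjusted p of 0.05 in edgeR and 0 calls in DESeq2 and limma voom. Rpl10 was at 0.01 under total-count scaling. Glycolysis (19 genes, 1 higher and 3 lower at an unadjusted p under 0.05, DESeq2 2 lower, limma voom 0), cholesterol biosynthesis (24 genes, 2 and 3, DESeq2 1 higher, limma voom 0) and complement genes (18 genes, 1 and 1, DESeq2 1 higher, limma voom 0) had none past the threshold over all genes or adjusted over the list alone. If normal diet replicate 2 was left out, 4 glycolysis and 5 cholesterol biosynthesis genes fell. Camera then called the glycolysis and ribosomal lists lower (0.00204 and 0.0347). Camera called the cell cycle list higher without high fat diet replicate 1 (0.0322) and without both that library and normal diet replicate 1 (0.00138). Its median was 0.54 with the hepatocyte score as a covariate. The glycolysis median (0.02) and mean (-0.10) differed in sign. Gapdh and Pkm were each at 0.13, with SEs of 0.12 and 0.15, Srebf2 and Insig1 at -0.20 ± 0.14 and -0.45 ± 0.18, and C1qb at -0.18 ± 0.16. Camera adjusted p-values of the ribosomal, cell cycle, glycolysis, cholesterol and complement lists were 0.265, 0.542, 0.483, 0.774 and 0.444, and that of nuclear oxidative phosphorylation genes was 0.348.

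Camera with the preset correlation called 24 of the 38 lists, 11 higher and 13 lower, and with an estimated correlation it called 0 (6 at an unadjusted p under 0.05, smallest adjusted p = 0.163). Fry, which tests whether the genes of a list move one way without comparing them with other genes, called 6. These were the lists of lipid uptake, storage and transport, lipid-associated macrophages, LXR targets, fatty acid oxidation, neutrophils, and immediate early and dissociation stress genes. Their adjusted p in fry lay between 0.0282 and 0.04. Fry was not run on other splits of the libraries. Splits of the libraries that mix the diets, described at the end, each gave between 13 and 24 lists in preset-correlation camera. A preset-correlation call alone therefore cannot be assigned to the diet.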

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

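All alternatives were fixed before the data were examined except edgeR without the robust prior, both tools without high fat diet replicate 1 and normal diet replicate 1 (the libraries of highest and lowest hepatocyte score), and DESeq2 with libraries left out, which were added after seeing the data. Under 3 other scalings, 2 other filters, limma voom and no robust prior, edgeR or voom called between 73 and 125 genes, against 91. DESeq2 called 1198 (733 higher, 465 lower, 669 at least 2-fold), and the cause was not tested. In simulated data DESeq2 also called more genes (251 against 181), with more false calls. The simulated genes varied independently of each other, without the shared variation of these libraries. The simulation therefore cannot show how many of the 1198 calls are false. With each library left out, the counts ran from 0 to 1385 changed, 0 to 519 higher, 0 to 866 lower and 0 to 461 at least 2-fold in edgeR, and from 537 to 2524 changed in DESeq2 (at least 89 of the 91 among them). The highest values came without normal diet replicate 2, and edgeR called 0 genes without high fat diet replicate 2 or normal diet replicate 1. With the hepatocyte score as a covariate edgeR called 0 in each of the 4 counts, with 1 degree of freedom fewer and a larger SE for 86 of the 91. All 91, selected for a diet difference in the same libraries, kept their sign. The log2 fold change was 1.84 ± 0.24 against 1.76 ± 0.14 for Cd36 and 2.29 ± 0.22 against 1.79 ± 0.20 for Fn1. It was 2.87 ± 0.36 against 2.41 ± 0.27 for Mmp12 and -1.98 ± 0.24 against -2.13 ± 0.16 for Itgae (SE). The hepatocyte scores of the diets did not overlap, so the fit cannot fully separate score from diet. Without high fat diet replicate 1 and normal diet replicate 1, edgeR called 0 in each and DESeq2 417 (332 higher, 85 lower, 328 at least 2-fold). Of the 32 named genes past the threshold, 29, 29 and 32 kept their call under median-ratio, upper-quartile and total-count scaling, 30 without a filter, 28 under the stricter filter (which tested 30), 32 in DESeq2 and 25 in limma voom. With libraries left out, 2, 0 and 0 kept it without high fat diet replicates 1, 2 and 3, and 0, 32 and 9 without normal diet replicates 1, 2 and 3. No named gene past the threshold changed sign in any of these. Medians of lists called by camera did: NK and innate lymphoid markers stood at 0.09 without normal diet replicate 3 (against -0.78), and stellate markers at 0.17 with the covariate (against -0.98). Hepatocyte markers stood at -0.11 with the covariate (against 1.60), which is the score of these same genes. Preset-correlation camera called between 23 and 26 of the 38 lists under the scalings, the stricter filter and each left-out library, but 0 with an estimated correlation, and fry called 6 (26 for change in either direction); the cause was not tested. The 91 genes all pass in the authors' deposited table at its adjusted and its unadjusted p. No paired analysis was possible because the labels give the libraries no shared replicate numbers. A pseudocount was not varied, since the tests used counts. Depth was similar in all libraries, and genes under about 7.02 mean normalised reads were not analysed here.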

Other observations

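Further genes past the threshold were chosen after their values were seen, and no list was tested for them. Slc27a1, a fatty acid transport protein, rose from 34.8 ± 6.90 to 76.6 ± 6.43 CPM, Angptl4, an inhibitor of lipoprotein lipase, from 11 ± 2.18 to 30.4 ± 2.76 CPM, and the lipoxygenase gene Alox15 from 33.8 ± 6.34 to 78.4 ± 11.3 CPM (SD, n = 3; edgeR adjusted p = 0.0430, 0.0351 and 0.0431). Atp6v0a1, a subunit of the lysosomal proton pump, rose 1.74-fold. Vnn1 and Acnat2, both of a hepatocyte lipid and xenobiotic response list, rose by log2 fold changes of 5.36 ± 0.35 and 5.48 ± 0.67 (SE).

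The interferon-inducible GTPase genes Gbp7 and Gbp8, also chosen after their values were seen, fell 1.59-fold and 1.71-fold (edgeR adjusted p = 0.0420 for each), and reads of this family may be shared. Nos2, the inducible nitric oxide synthase, was at 31.5 ± 23.7 CPM on the normal diet and 2.11 ± 0.80 CPM on the high fat diet, and the lectin gene Cd207 at 539 ± 265 and 111 ± 15.6 CPM (SD, n = 3), and neither passed (0.0902 and 0.0564).

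All tests in the paragraphs that follow were chosen after the results they concern had been seen, and the scores are means of log2 CPM with n = 3 libraries per diet.

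Hepatocyte transcripts were higher in the high fat diet libraries, and 3 of the 34 hepatocyte markers also stand in another list. Within the diets the markers moved together from library to library (median pairwise correlation of deviations from the group mean 0.97, against a 95th percentile of 0.08 for 1000 random lists). A varying share of hepatocyte RNA would move the marker genes so, but so would joint regulation. Camera's estimated correlation was 0.91 for hepatocyte markers. It was about as high for some other lists (0.91 for NK, 0.88 for endothelial and 0.86 for ribosomal genes) and lower for others. The correlation therefore cannot tell these explanations apart. The 21 tested genes of a hepatocyte lipid and xenobiotic response list, written after changed genes had been seen (9 rose, none fell), stood 1.32 ± 0.31 (SE) further above normal diet than the hepatocyte score, and all 16 tested Cyp2b, Cyp2c, Cyp3a and Cyp4a genes 1.2 ± 0.16. Both sets were chosen after large rises among them had been seen, and such a choice alone can give an excess. These values therefore cannot decide whether a varying share is the whole cause for these genes. For the mitochondrial transcripts the share cannot be told apart from a change within cells, since 6 libraries gave r = 0.53 with the hepatocyte score within diets (exact permutation p = 0.361, two-sided; Spearman rho = 0.43, exact permutation p = 0.333; smallest possible p = 0.0278; r = 0.60 without high fat diet replicate 1 and normal diet replicate 1). A candidate explanation for the marker genes is that the libraries held varying hepatocyte RNA; a response of hepatocytes to the diet stays open and needs isolated hepatocytes to test, and a gate or sort that would remove them is not given in the sources used here.

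Lipid-associated macrophage genes were higher in the high fat diet libraries, with scores of 8.12 ± 0.28 on the high fat diet and 6.91 ± 0.23 on the normal diet (SD). RNA from hepatocytes was tested by adjusting this score for the hepatocyte score, and the diet coefficient was 1.5 ± 0.31 (SE, 3 residual degrees of freedom), with a slope of -0.16 on the hepatocyte score. A higher share of macrophages would raise common macrophage genes alike, but the lipid-associated score stood 1.12 ± 0.27 (SE) further above normal diet than the common macrophage score. The first value argues against a larger share of hepatocyte RNA, as tracked by the marker genes. It cannot exclude hepatocyte genes that respond to the diet. In the same adjustment, the hepatocyte lipid and xenobiotic response list had a diet coefficient of 2.0 ± 0.24 (SE). Hepatocyte RNA therefore stays open for list members that hepatocytes also express. The second value argues against a higher share of macrophages. A change of macrophage state on the high fat diet, or the arrival of cells in that state, stays open as a hypothesis; these libraries do not separate the pair, and single-cell expression with lineage tracing would.

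MHC class II and interferon gamma response genes were lower in the high fat diet libraries, and 3 of 23 genes of an interferon gamma response list fell while none rose. Dilution of macrophage RNA by other cells would lower common macrophage genes alike, but their score did not fall (difference between diets 0.09 ± 0.11, SE). The MHC class II score less theirs differed by -0.96 ± 0.39 (SE), and by -1.34 without normal diet replicate 2. That difference rests on normal diet replicates 1 and 3 (-0.29 and -0.09). Normal diet replicate 2 (-1.33) lay near the high fat diet libraries (-1.66 to -1.44). These values argue only weakly against dilution. Fewer dendritic cells stay open. The MHC class II score less that of 8 genes taken as restricted to conventional dendritic cells differed by -0.05 ± 0.10 between diets (SE). Without normal diet replicate 2 the difference was -0.06. Of the 8 genes, 1 fell, Itgae, which also marks tissue T cells. A lower interferon gamma response stays open too: its score less that of 24 type I interferon response genes (0 past the threshold in edgeR) was -0.42 on the high fat diet and 0.42 on the normal diet (difference -0.83 ± 0.29, SE; -1.11 without normal diet replicate 2). The dendritic cell restricted list and both interferon lists were written after lower genes had been seen, so neither value supports its explanation, and the pair cannot be told apart without counts of dendritic cells.

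Splits of the 6 libraries into 3 and 3 were counted for each count of calls. The 10 possible splits are too few for a share under 0.05. The real split gave 91 genes changed (64 higher, 27 lower, 57 at least 2-fold) in edgeR and each of the 9 others gave 0, so 1 of the 10 splits gave as many for each of these counts. In DESeq2 the real split gave 1198 and the highest other 106. For lists past the preset-correlation camera threshold, the real split gave 24 and the 9 others between 13 and 24. The highest other came from high fat diet replicates 1 and 2 with normal diet replicate 2 against the rest. So 2 of the 10 splits gave as many. The count of lists called with the preset correlation therefore does not set the diets apart from other splits. Such a call alone cannot be assigned to the diet.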
